A study of Mus musculus with 8 samples.

How the data were processed

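Adipose-derived stem cells were obtained, per the labels' protocols, by digesting white fat with type II collagenase, lysing red blood cells and sorting the stromal vascular fraction by flow cytometry, and their RNA was sequenced in bulk. The series holds 8 samples from 4 depots with 2 replicates each, of male wild-type C57BL/6J mice on chow. The surface markers of the gate, the library kit and its strandedness, the aligner, the counting program and the annotation are not given in the sources used here. Genome build GRCm38.p6, Cell Ranger and Seurat are named, without versions or roles, per the submitters' processing notes.

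The authors deposited a table of estimated counts per gene symbol, per the file headers, whose values are not normalized and are 31.7% to 33.1% not whole. They also deposited a table of FPKM values per gene symbol, per the file headers, which divide the read counts by gene length and library size. After scaling each library by a constant, 95.9% of FPKM values over 9473 genes with at least 100 counts in each library had a ratio to the count within 5% of the gene's mean ratio, so the tables describe the same libraries. There were 2 columns per table with a letter that matches no label, and these were left out of every step. The mesenteric depot is therefore not analysed here, and comparisons planned against the mean of 3 other depots became comparisons against the mean of 2. The remaining 6 columns were matched to inguinal (SWAT), epididymal (EWAT) and perirenal (NWAT) samples by depot letter and replicate number.

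The tables list 17967 symbols, of which 17503 matched a symbol in the RefSeq annotation of GRCm38.p6 and 17777 a symbol or synonym. Coordinates come from that annotation. A symbol listed more than once was read from the entry with the higher total, and 11 symbols had been turned into dates and were kept as they stand. Because the strand setting of the counting is unknown, reads of overlapping and antisense genes cannot be told apart, and near-identical copies such as C4b and C4a, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Hspa1a and Hspa1b may share reads. Library totals were 20428508 and 20638724 for SWAT, 20346519 and 20583224 for EWAT and 20176545 and 20026413 for NWAT. Estimated counts were rounded to whole numbers before testing.

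Tests were run in R 4.3.3. The choices of tests, gene lists, naming rule and alternatives were made before the data were examined, except where stated. Counts were scaled by TMM factors (0.893 and 0.919 for SWAT, 1.05 and 1.08 for EWAT, 1.04 and 1.03 for NWAT) in edgeR 4.0.16 and filtered with filterByExpr by depot, with a count minimum of 10 and a total minimum of 15, which left 13694 genes. A quasi-likelihood model with 1 coefficient per depot was fitted to all 6 libraries with robust dispersion estimates, leaving 3 residual degrees of freedom, and the common biological coefficient of variation was 0.0979. Contrasts were the joint test, each depot against the mean of the other 2 and each pair of depots, with Benjamini-Hochberg adjustment at 0.05. A gene was set apart in a depot if it differed from each of the others in the same direction. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic, and levels are TMM-scaled CPM with the SD over 2 libraries. Where a depot had 0 counts, a fold is given as a bound against a floor of 3 counts per library. Ratios resting on few counts carry exact 95% intervals from the counts of both depots.

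For each depot the genes named in the text were those that passed against the mean and against each other depot, with a mean log2 CPM of at least 2 and without provisional symbols, ranked by the smaller pairwise change, the first 12 higher and 6 lower. For each pair the 3 highest and 3 lowest were named under the same minimum. Members of fixed lists are named as examples of their list, picked after their values were seen. Values of some list members are not reported here. The 39 fixed lists cover pathways, regulators and 14 other cell types, and the 31 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and the self-contained fry test were run beside it. Some lists share members, so their results are not independent. The Icam1-type and basement membrane lists share Col4a1, Col4a2, Col15a1 and Sparcl1. The complement and macrophage lists share C1qa, C1qb and C1qc, and the visceral and mesothelial lists share Wt1 and Bnc1. Further overlaps include Wnt2 (Dpp4-type and Wnt), Cd55 (Dpp4-type and complement), Dlk1 (Icam1-type and imprinted), Rspo1 (Wnt and mesothelial) and Hoxc9 (thermogenic and Hox).

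On simulated data with the real means and library sizes, for SWAT against the mean of EWAT and NWAT over 13497 genes, edgeR recovered 38 of 67 genes changed 1.5-fold, 51 of 67 changed 2-fold and 63 of 66 changed 4-fold, and 14 of its 182 calls were false (7.69%). The other 16 calls were members of a further planted list of 20 genes changed 1.5-fold, which was called by camera over 31 lists (camera adjusted p = 2.7e-24; adjusted p = 0.044 with an estimated correlation), with 0 of the other lists called. The simulated genes varied independently of each other. The simulation therefore could not show list calls that arise from correlation between genes. Far fewer genes were called in it than the 3815 of the same comparison in the data, which makes the adjusted threshold stricter. Its recovered and false shares therefore need not hold for the data. Replicates of a depot differed by more than counting noise, with a chi-square per degree of freedom of 9.11 in SWAT, 19.1 in EWAT and 12.1 in NWAT. That spread may be technical, so it cannot tell separate samples from repeats of 1 sample. Each library was treated as a sample of its own.

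Alternatives were DESeq2 size factors, no filter beyond 1 count, a stricter filter of at least 1 CPM in 4 libraries, a replicate block, non-robust fits, DESeq2 1.42.0, limma-voom, limma on log2 (FPKM + 1) for genes above 1 FPKM in 2 libraries, on log2 (FPKM + 0.1) and without a filter, an absolute log2 fold change above 1, the 4 libraries of a pair alone, and leaving out each library in turn. Fits with each library's trend on transcript length or GC content removed were added after seeing the data, with lengths from GENCODE M21 available for 98.4% of the tested genes.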

Results

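Gene expression was measured by bulk RNA sequencing in adipose-derived stem cells, the fibroblast-like progenitors that can give rise to adipocytes. The cells were sorted by flow cytometry from the stromal vascular fraction of white fat of male wild-type C57BL/6J mice kept on chow. The depots analysed here were subcutaneous inguinal fat (SWAT), epididymal fat (EWAT) and perirenal fat (NWAT), with 2 libraries each, 6 in all. Library totals lay between 20026413 and 20638724 estimated read counts, and 15858 to 16228 genes had a count in each library. In SWAT the most abundant transcript was that of the fibrillar collagen gene Col3a1, with 4.86% and 4.90% of the counts, whereas in EWAT and NWAT it was that of Gsn, which codes for the actin-severing protein gelsolin. The 6 fibrillar collagen genes Col1a1, Col1a2, Col3a1, Col5a1, Col5a2 and Col5a3 together took 10.8% ± 0.171 of the counts in SWAT, 3.34% ± 0.191 in EWAT and 4.0% ± 0.0201 in NWAT (SD, n = 2). No source says that the replicates of a depot came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The counting intervals of folds between depots, and the floors, cover counting error only.

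The 3 depots separated by their whole transcriptomes. The first principal component held 61.3% of the variance and placed SWAT opposite EWAT, and the second held 24.4% and placed NWAT apart from both. Correlations of log2 CPM (read counts scaled to library size) over genes were 0.988 to 0.991 within a depot and 0.924 to 0.963 between depots. Of 13694 genes tested, 5689 (41.5%) differed among the depots in the joint test of edgeR's quasi-likelihood model at a Benjamini-Hochberg adjusted p under 0.05, the threshold for every call below. Each depot was then set against the mean of the other 2 depots.

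**Figure D1:**
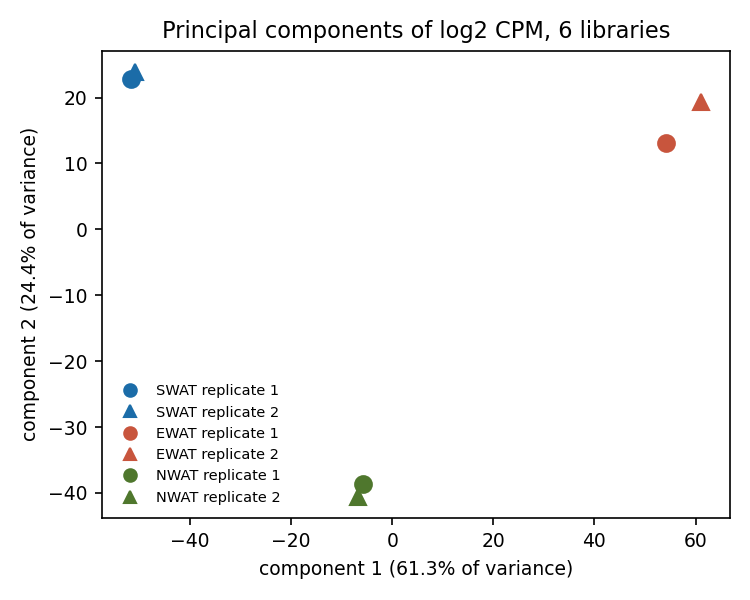
The first and second principal components of log2 CPM are plotted for the 6 libraries, with circles for replicate 1 and triangles for replicate 2. The components hold 61.3% and 24.4% of the variance, and both libraries of each depot lie closer to each other than to any library of another depot.

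Stem cells of SWAT carried high levels of limb-type patterning regulators and of fibrillar collagens, and almost no transcripts of Wt1 and Tcf21, transcription factors that act in the embryonic coelomic and urogenital mesenchyme. Tbx15, a T-box factor of skeletal and fat patterning, stood at 112 CPM ± 9.79 (SD, n = 2) in SWAT, 9.70 CPM in NWAT and 0.508 CPM in EWAT. Shox2, a homeobox regulator of limb growth, stood at 54.6 CPM ± 3.55 in SWAT and was 298-fold (95% counting interval 151 to 692) higher there than in EWAT and 189-fold (108 to 367) higher than in NWAT. Wt1 had 0 counts in both SWAT libraries, against 156 CPM ± 6.45 in EWAT and 121 CPM ± 20.5 in NWAT, and so was at least 968.9-fold higher in EWAT and at least 749.3-fold higher in NWAT with a floor of 3 counts per library. Tcf21 had 5 counts over both SWAT libraries and was 2717-fold (1164 to 8370) higher in EWAT and 838-fold (359 to 2582) higher in NWAT.

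Among genes with a mean log2 CPM of at least 2, the 12 that most clearly marked SWAT were ranked by the smaller of their differences from EWAT and NWAT. Tbx15 had the largest log2 fold change against their mean, 5.66 ± 0.14 (SE; edgeR adjusted p = 1.36e-09). Mmp3, the matrix protease stromelysin, followed at 5.25 ± 0.19 (edgeR adjusted p = 1.24e-07), with 685 CPM in SWAT, 65.9 in NWAT and 4.90 in EWAT. Il1r2, the decoy receptor for interleukin-1, was higher by 4.71 ± 0.15, Abcc9, a subunit of ATP-sensitive potassium channels, by 4.56 ± 0.17, and Plin4, a lipid droplet coat protein, by 4.25 ± 0.24. Prg4, which codes for the lubricant lubricin, was higher by 4.21 ± 0.32, and Wisp2, a secreted matricellular protein, by 3.84 ± 0.11. The other 5 were Itga7, a laminin receptor subunit, Osr2, an odd-skipped zinc finger factor, Prkg2, a cGMP-dependent kinase, C4b, complement component 4, and Cldn10, a claudin, at 3.04 to 3.55. C4b reads may be shared with its near-identical copy C4a. Besides Wt1 and Tcf21, the 6 lowest genes were Hp, which codes for the haemoglobin-binding protein haptoglobin (-7.10 ± 0.16, edgeR adjusted p = 7.21e-10), the collagen VI gene Col6a5 (-6.06 ± 0.16), the cytochrome P450 gene Cyp2s1 (-5.24 ± 0.20) and Lrrn2 (-4.47 ± 0.15). For these 12 and 6 genes, both SWAT libraries lay beyond all 4 others, which chance gives for 6.67% of genes per direction, though the genes were chosen by the same test. On GRCm38.p6, the protein-coding genes Tbx15 (chromosome 3, 99240348 to 99354260), Mmp3 (chromosome 9, 7445822 to 7455975), Wt1 (chromosome 2, 105126529 to 105173614), Tcf21 (chromosome 10, 22817263 to 22820143) and Hp (chromosome 8, 109575128 to 109579172) are annotated at these places.

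**Figure D2:**
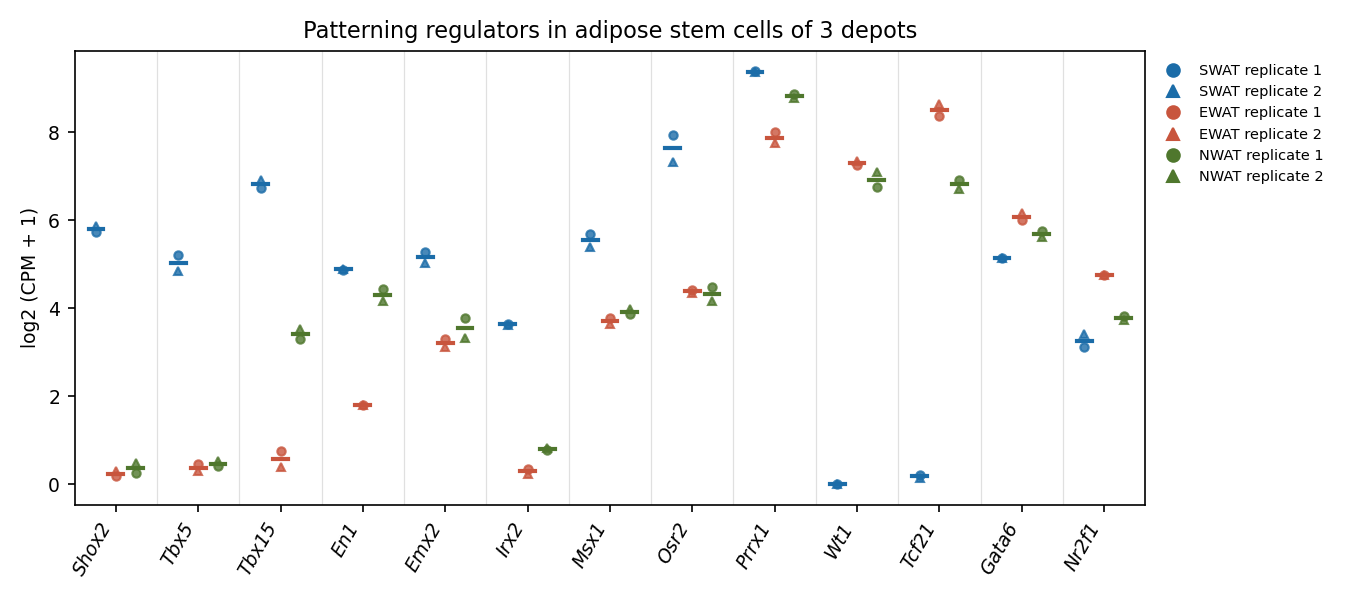
Levels of 13 patterning regulators are plotted as log2 (CPM + 1) for each library, with circles for replicate 1, triangles for replicate 2 and a bar at the mean of each depot. Shox2, Tbx5 and Tbx15 are highest in SWAT, and Wt1 has 0 counts in both SWAT libraries against 156 CPM in EWAT and 121 CPM in NWAT.

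Of the 39 fixed gene lists, 31 had at least 5 tested members, and 8 were past the threshold in SWAT, 5 higher and 3 lower, by limma's camera test. With an estimated correlation the camera test called 0 of the lists in each depot, with 5, 4 and 2 at an unadjusted p under 0.05 in SWAT, EWAT and NWAT, and limma's fry test called 11, 15 and 15. Within the lists, 16 of 20 tested subcutaneous and limb-type patterning regulators were higher in SWAT, 17 when adjusted over the list alone, with a median log2 fold change of 1.97. The list was past the threshold (camera adjusted p = 1.05e-12; adjusted p = 0.223 with an estimated correlation). Its members included Tbx5, at 31.9 CPM ± 5.82 in SWAT and 107-fold (62.2 to 201) higher than in EWAT, En1 (2.06 ± 0.11), Emx2 (1.88 ± 0.14) and Prrx1 (1.02 ± 0.10). Visceral and coelomic patterning regulators were lower, with 8 of 17 members lower and 3 higher, and 9 and 3 adjusted over the list alone. The median was -0.76 (camera adjusted p = 0.00379; adjusted p = 0.234 with an estimated correlation). Besides Wt1 and Tcf21, the lower members included Foxf1 (-2.08 ± 0.34), Nr2f1 (-1.07 ± 0.12) and Gata6 (-0.76 ± 0.10), while Osr2, Hand2 and Bnc2 (0.45 ± 0.10) were higher. Mesothelial markers moved with these genes, and 10 of 13 were lower in SWAT and 1 higher, 10 and 2 adjusted over the list alone. Their median was -3.66, or -2.40 with members at 0 counts set to their bound (camera adjusted p = 8.66e-07; adjusted p = 0.223 with an estimated correlation). Rspo1 (-3.35 ± 0.12) and Ezr (-2.40 ± 0.11) were lower, and Cldn15 (0.47 ± 0.13) was higher. The call of Bnc2 was lost without SWAT replicate 2 (0.37), and that of Cldn15 without SWAT replicate 2 (0.29), EWAT replicate 1 (0.41) or NWAT replicate 1 (0.39), and both were lost on log2 (FPKM + 1) values (0.21 and 0.25).

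Fibrillar and interstitial matrix genes were higher in SWAT for 16 of 29 members and lower for 6, or 17 and 6 adjusted over the list alone. The median was 0.45 (camera adjusted p = 3.06e-04; adjusted p = 0.223 with an estimated correlation). Col1a1 (2.43 ± 0.13), Col6a3 (1.89 ± 0.11) and Col3a1 (1.67 ± 0.11) rose, whereas Thbs1, a secreted thrombospondin, fell (-2.95 ± 0.16), with 188 CPM in SWAT, 1595 in EWAT and 1321 in NWAT. Without SWAT replicate 2, 2 of the members were lower. Thermogenic and beige or brown genes were higher for 7 of 12 members over all genes and adjusted over the list alone. The median was 1.33 (camera adjusted p = 4.64e-04; adjusted p = 0.223 with an estimated correlation). Those 7 were Tmem26 (2.88 ± 0.11, 44.1 CPM in SWAT), Prdm16 (1.57 ± 0.15), Tbx1, Lhx8, Cited1, Cox8b and Hoxc9, whose call was lost without SWAT replicate 1 (0.46), and the thermogenic uncoupler Ucp1 had too few counts to be tested (0 and 0 in SWAT, 1 and 1 in EWAT, 6 and 7 in NWAT). This list's call was lost with no count filter (camera adjusted p = 0.190) and with a stricter filter (0.135), within a range of 4.84e-04 to 0.223 over 14 alternatives, and its median was 0.88 without SWAT replicate 2.

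Basement membrane genes were higher for 10 of 19 members and lower for 2, or 10 and 3 adjusted over the list alone. The median was 0.34 (camera adjusted p = 0.0218; adjusted p = 0.832 with an estimated correlation), with Hspg2 (1.13 ± 0.13), which codes for perlecan, and Col18a1 (0.95 ± 0.11) higher and Col4a6 (-2.28 ± 0.11) lower. The list was not past the threshold without EWAT replicate 2 (camera adjusted p = 0.0549) or with the length trend removed (0.0617), within 0.0109 to 0.832 over 14 alternatives. Icam1-type committed preadipocyte markers were higher for 8 of 15 members and lower for 1, or 8 and 2 adjusted over the list alone. The median was 0.44 (camera adjusted p = 0.0254; adjusted p = 0.832 with an estimated correlation). Icam1 (0.96 ± 0.12) and Pparg (1.06 ± 0.15), the nuclear receptor that drives adipogenesis, rose and Vcam1 (-0.40 ± 0.11) fell. Vcam1 lost its call without SWAT replicate 1 (-0.32), SWAT replicate 2 (-0.47) or NWAT replicate 2 (-0.31), and the list's call was lost without SWAT replicate 2 (camera adjusted p = 0.167) or EWAT replicate 1 (0.090), within 8.83e-04 to 0.832. Macrophage and monocyte markers were lower for 3 of 16 members over all genes and adjusted over the list alone, namely Fcer1g, Lyz2 and H2-Aa. Lyz2 lost its call without SWAT replicate 1 (-0.93), and H2-Aa without SWAT replicate 1 (-0.68), SWAT replicate 2 (-1.02) or NWAT replicate 1 (-0.70) and in DESeq2 (-0.83). The median was -0.32 (camera adjusted p = 0.0298; adjusted p = 0.832 with an estimated correlation). That call was lost without SWAT replicate 1 (camera adjusted p = 0.136), EWAT replicate 1 (0.0684), EWAT replicate 2 (0.0657) or NWAT replicate 1 (0.168), with a stricter filter (0.144) and with the length trend removed (0.0599), within 1.68e-04 to 0.832, and its median was -0.66 without SWAT replicate 2 and -0.56 without NWAT replicate 2. The fry test also called the F3-type list higher (fry adjusted p = 0.0249; camera adjusted p = 0.176) and the Wnt list lower (0.0328; 0.740). It did not call the basement membrane (fry adjusted p = 0.0959), Icam1-type (0.0907) or macrophage list (0.140) in SWAT. In 7 of the 8 lists past the threshold the list medians of both SWAT libraries lay beyond those of the other 4, the exception being the macrophage and monocyte markers. These lists were picked by a test on the same libraries.

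Over all genes, edgeR called 3815 in SWAT against the mean of EWAT and NWAT, 1919 higher and 1896 lower. By the pairwise tests, 1632 genes were set apart from each of the other depots in the same direction, 854 higher and 778 lower. The numbers fell to 2063 and 994 without SWAT replicate 1 and to 2001 and 918 without SWAT replicate 2, and the genes set apart fell to 1066 without NWAT replicate 1 and 1012 without NWAT replicate 2. In limma on log2 (FPKM + 1) values, which share no TMM scaling, log2 fold changes were compared with those of the counts. The median difference over 11554 genes was -0.196 for SWAT, 0.128 for EWAT and 0.0673 for NWAT. For the pairs it was -0.216 for SWAT against EWAT, -0.175 for SWAT against NWAT and 0.0403 for EWAT against NWAT. Of the calls in SWAT on these values, 15.2% were higher, against 50.3% from the counts. The split into higher and lower calls therefore depends on the scaling.

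Stem cells of EWAT had raised levels of Tcf21 and of most Hox genes of paralogue groups 1 to 8, and their libraries held more transcripts of macrophage markers, at low levels. Levels of limb-type regulators, interferon-response genes and markers of interstitial progenitors were low. Lrrn1, which codes for a leucine-rich repeat membrane protein, stood at 69.3 CPM ± 9.86 (SD, n = 2) in EWAT, 4.46 CPM in SWAT and 1.39 CPM in NWAT. Aldh1a2, the enzyme that makes retinoic acid from retinaldehyde, stood at 30.1 CPM against 1.79 and 2.81. Mgp, the matrix inhibitor of calcification, stood at 208 CPM against 7.06 and 27.3. Bmp3, a BMP-family ligand, was 64.9-fold (38.4 to 119) higher in SWAT and 34.0-fold (20.1 to 62.7) higher in NWAT than in EWAT.

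In the 12 genes that most clearly marked EWAT, log2 fold changes against the mean of SWAT and NWAT ran from 3.0 ± 0.15 for Rem1, a small GTPase, to 4.79 ± 0.15 for Lrrn1 (edgeR adjusted p = 4.47e-09). They included Mgp (3.90 ± 0.14), Trf, the iron carrier transferrin (3.74 ± 0.10), Aldh1a2 (3.74 ± 0.18), Ccbe1, a secreted factor of lymphatic growth (3.54 ± 0.10), and Sult1e1, the oestrogen sulfotransferase (3.13 ± 0.10). The others were Fmod, the collagen-binding proteoglycan fibromodulin, Egflam, the matrix protein pikachurin, Tmem204, the potassium channel gene Kcnk2 and the cationic amino acid transporter gene Slc7a2, at 3.17 to 3.65. The 6 lowest genes were Tbx15 (-6.02 ± 0.22, edgeR adjusted p = 9.32e-09), Bmp3 (-5.53 ± 0.46, 3.41e-05), the progesterone-inactivating enzyme gene Akr1c18 (-5.29 ± 0.33), the protocadherin gene Pcdh20 (-4.98 ± 0.16), Hoxa10 (-4.47 ± 0.19) and Cxcl13, a B-cell attracting chemokine (-4.29 ± 0.26). In all 12 and 6 genes both EWAT libraries lay beyond the other 4, though these genes too were chosen by the same test. On GRCm38.p6, Lrrn1 lies on chromosome 6 from 107529726 to 107570228, Aldh1a2 on chromosome 9 from 71215789 to 71296243, Mgp on chromosome 6 from 136872435 to 136875823 and Bmp3 on chromosome 5 from 98854415 to 98884053, all protein-coding.

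In EWAT 11 lists were past the threshold, 5 higher and 6 lower. Subcutaneous and limb-type patterning regulators were lower for 16 of 20 members, the same number adjusted over the list alone. The median was -1.79 (camera adjusted p = 1.96e-09; adjusted p = 0.288 with an estimated correlation), among them En1 (-3.22 ± 0.15) and Prrx1 (-1.22 ± 0.11). Visceral and coelomic regulators were higher for 9 of 17 members and lower for 2, or 10 and 2 adjusted over the list alone. The median was 0.68 (camera adjusted p = 0.0315; adjusted p = 0.402 with an estimated correlation), with Tcf21 (6.52 ± 0.15), Nr2f1 (1.30 ± 0.11) and Gata6 (0.68 ± 0.09) higher and Osr2 (-1.64 ± 0.18; call lost without EWAT replicate 2, -1.61) and Hlx lower. This call was lost without SWAT replicate 1 (camera adjusted p = 0.108), SWAT replicate 2 (0.139, median 0.22), EWAT replicate 1 (0.298, median 0.27) or NWAT replicate 2 (0.151, median 0.20), with no filter (0.0918) and with the length trend removed (0.0579), within 0.00170 to 0.402 over 14 alternatives. Mesothelial markers were higher for 10 of 13 members and lower for 1, over all genes and adjusted over the list alone. The median was 2.82, or 1.45 with members at 0 counts set to their bound (camera adjusted p = 2.96e-04; adjusted p = 0.377 with an estimated correlation). Rspo1 (2.45 ± 0.09) and Ezr (1.65 ± 0.09) rose and Krt19 (-2.64 ± 0.24) fell, and the mesothelial surface marker Msln stood at 1.28 CPM in EWAT, 0.769 in NWAT and 0.0264 in SWAT.

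Hox genes, which set position along the body axis, split by their place in the clusters. Of 28 tested, 17 were higher and 6 lower in EWAT, 17 and 7 adjusted over the list alone. The median was 0.62 (camera adjusted p = 0.0291; adjusted p = 0.654 with an estimated correlation). The mean log2 fold change was 0.0059, and the fry test pointed the other way (fry adjusted p = 0.707). The camera call was lost without EWAT replicate 1 (camera adjusted p = 0.129), with no filter (0.0918) and with the length trend removed (0.0534), within 0.00590 to 0.707 over 14 alternatives. In a split of the list chosen after its values were seen, 16 of 21 genes of paralogue groups 1 to 8 were higher in EWAT (median 0.83), among them Hoxb5 (2.72 ± 0.24), Hoxa5 (1.56 ± 0.14) and Hoxc4 (0.72 ± 0.09). In groups 9 to 13, 6 of 7 were lower and 1, Hoxd9 (0.97 ± 0.24; call lost without EWAT replicate 2, 0.98), was higher (median -3.08). Among the lower ones, Hoxa11 (-1.50 ± 0.46) lost its call without SWAT replicate 1 (-1.31), EWAT replicate 2 (-1.13) or NWAT replicate 1 (-1.39) and in DESeq2 (-1.53). Hoxc10 stood at 56.1 CPM in SWAT, 25.7 in NWAT and 2.08 in EWAT (-4.18 ± 0.14, edgeR adjusted p = 4.47e-09), and Hoxa9 was lower by -3.08 ± 0.18. For SWAT, groups 1 to 8 had 1 gene higher and 10 lower, and groups 9 to 13 had 5 higher and 1 lower. The Hox list as a whole was not past the threshold in SWAT or in NWAT.

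**Figure D3:**
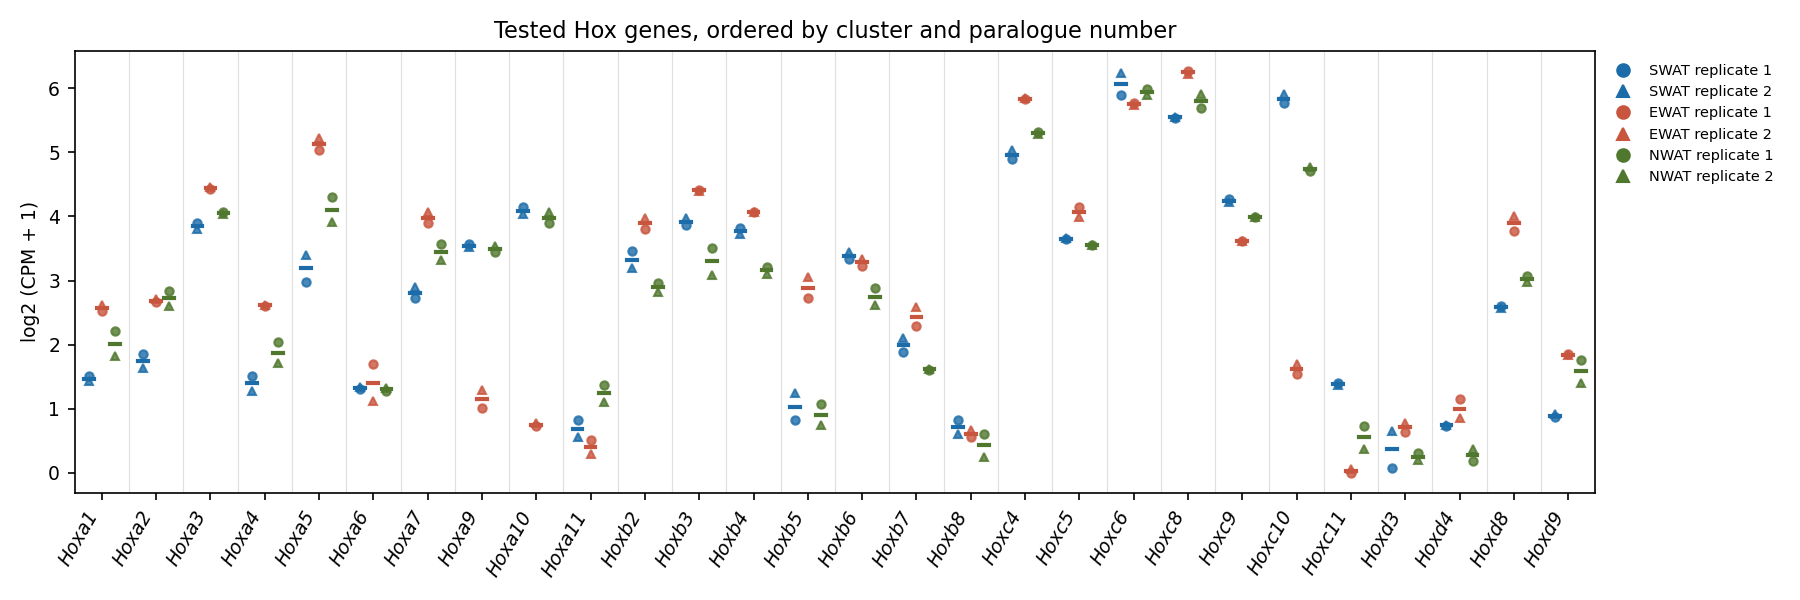
The 28 tested Hox genes are ordered by cluster and paralogue number, with levels as log2 (CPM + 1) per library, circles for replicate 1, triangles for replicate 2 and a bar at each depot's mean. Hoxa9, Hoxa10, Hoxa11, Hoxc9, Hoxc10 and Hoxc11 are lower in EWAT, where Hoxc10 stands at 2.08 CPM against 56.1 CPM in SWAT and 25.7 CPM in NWAT.

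Interferon-response genes were lower in EWAT for 20 of 22 members, 21 adjusted over the list alone. The median was -0.83 (camera adjusted p = 2.48e-07; adjusted p = 0.654 with an estimated correlation), with Ifit1 (-1.82 ± 0.27) and Oas1a (-1.72 ± 0.20) as examples. Ifit1 lost its call without EWAT replicate 1 (-1.62) or EWAT replicate 2 (-2.06). Markers of Dpp4-type interstitial progenitors, cells described upstream of committed preadipocytes, were lower for 15 of 17, and 16 adjusted over the list alone. The median was -0.76 (camera adjusted p = 2.58e-07; adjusted p = 0.654 with an estimated correlation). Pi16 stood at 592 CPM in EWAT, 1930 in SWAT and 3363 in NWAT, Dpp4 at 232, 490 and 691 CPM, and the Wnt ligand gene Wnt2 at 4.12, 51.4 and 30.3 CPM. Imprinted growth-related genes were lower for 8 of 13 members over all genes and adjusted over the list alone. The median was -0.54 (camera adjusted p = 0.00131; adjusted p = 0.288 with an estimated correlation), among them Plagl1 (-2.27 ± 0.10), Peg3 (-0.97 ± 0.14) and Grb10 (-0.67 ± 0.10). Thermogenic genes were lower for 6 of 12 and higher for 1, or 6 and 2 adjusted over the list alone. The median was -0.82, or -1.14 at the bound (camera adjusted p = 0.00199; adjusted p = 0.288 with an estimated correlation), with Tmem26 (-3.22 ± 0.14) and Prdm16 (-1.36 ± 0.18) lower and Ppargc1a (1.11 ± 0.30; call lost without EWAT replicate 1, 1.0), a coactivator of mitochondrial genes, higher. The thermogenic call was lost with no filter (camera adjusted p = 0.163) and with a stricter one (0.0930), within 0.00142 to 0.288, and its median was -0.51 without EWAT replicate 2.

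Fibrillar and interstitial matrix genes were lower in EWAT for 18 of 29 and higher for 6, or 21 and 7 adjusted over the list alone. The median was -0.48 (camera adjusted p = 0.00239; adjusted p = 0.288 with an estimated correlation). Col12a1 (-2.57 ± 0.12), Thbs2 (-2.09 ± 0.11) and Col1a1 (-1.63 ± 0.15) fell, whereas the elastic fibre gene Mfap4 (2.74 ± 0.12) and the small proteoglycan genes Bgn (1.17 ± 0.10) and Dcn (0.79 ± 0.11) rose. Macrophage and monocyte markers were higher for 13 of 16 members over all genes and adjusted over the list alone. The median was 1.28 (camera adjusted p = 1.23e-05; adjusted p = 0.654 with an estimated correlation). Their levels were low, with the lysozyme gene Lyz2 at 8.50 CPM in EWAT, 1.76 in SWAT and 2.18 in NWAT, Cd74 at 10.4, 5.07 and 4.08 CPM, and the pan-leukocyte gene Ptprc at 0.847, 0.269 and 0.361 CPM. Ptprc (1.43 ± 0.39) lost its call without SWAT replicate 2 (1.41), EWAT replicate 1 (1.44) or EWAT replicate 2 (1.41) and in DESeq2 (1.44), and Dcn lost its own on unfiltered log2 (FPKM + 1) values (0.93). Pericyte and smooth muscle markers were higher for 7 of 11 members and lower for 3, with a median of 1.22, and were called by fry (fry adjusted p = 0.0344) but not by camera (camera adjusted p = 0.213). The same held for the F3-type (fry adjusted p = 0.0370; camera adjusted p = 0.253) and complement lists (0.0297; 0.770), both higher by fry. Oxidative phosphorylation genes were higher for 18 of 28 members, 23 adjusted over the list alone. The median was 0.37 (camera adjusted p = 9.63e-05; adjusted p = 0.703 with an estimated correlation), including Uqcrb (0.70 ± 0.14) and Ndufa4 (0.68 ± 0.15). All 28 were higher in EWAT replicate 2 than in replicate 1, and 8 of 28 were called without SWAT replicate 2, 7 without NWAT replicate 1 and 3 without EWAT replicate 2, where the median was 0.16, Ndufa4 (0.35) was not called and Uqcrb stood at 0.39. The fry test did not call the oxidative phosphorylation list (fry adjusted p = 0.0932). Within these lists, the 11 past the threshold all had both EWAT libraries beyond the other 4 by their median member, though a test on the same libraries picked them.

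Over all genes, edgeR called 4964 in EWAT against the mean of SWAT and NWAT, 2598 higher and 2366 lower, and 2399 were set apart from each other depot, 1233 higher and 1166 lower. Without EWAT replicate 2 these numbers fell to 2994 and 1543, and the genes set apart fell to 1461 without NWAT replicate 1 and 1566 without NWAT replicate 2. On log2 (FPKM + 1) values, 74.5% of the calls in EWAT were higher, against 52.3% from the counts.

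Stem cells of NWAT showed high levels of interstitial progenitor markers, interferon-response genes, Wnt regulators and imprinted growth-related genes, and low levels of committed preadipocyte and basement membrane genes. Pericyte markers were also lower in these libraries. The imprinted cell cycle inhibitor gene Cdkn1c stood at 113 CPM ± 9.35 (SD, n = 2) in NWAT, 24.6 CPM in SWAT and 36.1 CPM in EWAT. Wnt2b, a canonical Wnt ligand gene, stood at 15 CPM ± 5.64 against 2.23 and 3.73, and the neutrophil chemokine gene Cxcl2 at 37.4 CPM ± 13.6 against 8.15 and 7.89. Myh11, the smooth muscle myosin heavy chain gene, stood at 1.46 CPM in NWAT, 4.45 in SWAT and 25.4 in EWAT.

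For the 12 genes that most clearly marked NWAT, log2 fold changes against the mean of SWAT and EWAT lay between 1.67 ± 0.16 for Prr5l and 3.19 ± 0.18 for Parm1, a mucin-like membrane protein gene (edgeR adjusted p = 1.21e-06). Next came Thsd4, a microfibril-associated protein gene (2.75 ± 0.16), Asb4, a ubiquitin ligase adaptor gene (2.57 ± 0.15), Wnt2b (2.37 ± 0.21), Igsf1 (2.35 ± 0.12), Cxcl2 (2.22 ± 0.22, edgeR adjusted p = 2.92e-04) and the pentraxin gene Nptx2 (2.14 ± 0.09). The rest were Sipa1l2, Cdkn1c (1.92 ± 0.09), the metalloprotease gene Adamts16 and the interferon-induced GTPase gene Gbp5. The 6 lowest were Wisp2 (-3.48 ± 0.15, edgeR adjusted p = 3.97e-07), Fam107a (-2.92 ± 0.19), Ism1 (-2.36 ± 0.11), the neuropeptide gene Nmb (-2.29 ± 0.13), the endothelin receptor gene Ednra (-2.16 ± 0.18) and Angpt1, a ligand of the endothelial receptor Tek (-2.16 ± 0.11). Both NWAT libraries lay beyond the other 4 for all 12 and 6, genes again chosen by the same test. On GRCm38.p6, the protein-coding gene Parm1 lies on chromosome 5 from 91517700 to 91624011, Cdkn1c on chromosome 7 from 143458339 to 143461059, Wnt2b on chromosome 3 from 104944805 to 104961709 and Wisp2 on chromosome 2 from 163820752 to 163833146.

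In NWAT 16 lists were past the threshold, 6 higher and 10 lower. Genes low in EWAT alone can count as higher in NWAT against a mean. Dpp4-type, interferon and imprinted calls in these depots are therefore partly the same result. By the levels above, Wnt2 was higher in SWAT than in NWAT. By the median Dpp4-type member against its gene mean, NWAT (0.67 and 0.49) lay above SWAT (0.22 and -0.11) and EWAT (-0.58 in both). Dpp4-type interstitial progenitor markers were higher for 15 of 17 members, and for 17 adjusted over the list alone. The median was 0.92 (camera adjusted p = 2.15e-10; adjusted p = 0.502 with an estimated correlation), with Pi16 (1.65 ± 0.12), Sema3c (1.39 ± 0.09) and Dpp4 (1.03 ± 0.10) as examples. Icam1-type committed preadipocyte markers were lower for 8 of 15 and higher for 1, or 10 and 1 adjusted over the list alone. The median was -0.64 (camera adjusted p = 1.24e-04; adjusted p = 0.534 with an estimated correlation), with Apoe (-1.60 ± 0.15) and Col15a1 (-0.95 ± 0.11) lower and Dlk1 (2.69 ± 0.39), an inhibitor of adipogenesis, higher. Without NWAT replicate 1, 5 were lower. F3-type regulatory cell markers were lower for 6 of 10 and higher for 2, or 7 and 2 adjusted over the list alone. The median was -1.15 (camera adjusted p = 0.00291; adjusted p = 0.483 with an estimated correlation), with Gas6 (-1.76 ± 0.10) and Gdf10 (-1.36 ± 0.11) lower and Igfbp3 (2.26 ± 0.14) and Meox2 (0.89 ± 0.12) higher. Wnt pathway ligands and modulators were higher for 11 of 21 and lower for 2, or 12 and 2 adjusted over the list alone. The median was 0.59 (camera adjusted p = 1.24e-04; adjusted p = 0.483 with an estimated correlation), with Dkk2 (1.93 ± 0.09), Sfrp4 (1.19 ± 0.11) and Wnt10b (1.09 ± 0.10) higher and Rspo2 (-2.07 ± 0.33) and Wnt5b (-0.80 ± 0.19) lower. Wnt5b lost its call without EWAT replicate 2 (-0.75) or NWAT replicate 2 (-0.48), and stood at -1.23 without NWAT replicate 1. Imprinted growth-related genes were higher for 8 of 13 members over all genes and adjusted over the list alone. The median was 0.78 (camera adjusted p = 1.24e-04; adjusted p = 0.483 with an estimated correlation), including Plagl1 (1.55 ± 0.09), Mest (1.44 ± 0.09) and Grb10 (0.94 ± 0.10).

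Interferon-response genes were higher in NWAT for 21 of 22 members over all genes and adjusted over the list alone. The median was 0.84 (camera adjusted p = 2.34e-10; adjusted p = 0.534 with an estimated correlation). Ifit1 (1.82 ± 0.23) stood at 176 CPM ± 72.3 in NWAT, 76.0 in SWAT and 32.7 in EWAT, and Rsad2 (1.64 ± 0.16) and Iigp1 (1.16 ± 0.14) rose too. Ifit1 lost its call without EWAT replicate 1 (1.72) or EWAT replicate 2 (1.93). All 22 were higher in NWAT replicate 2 than in replicate 1, and without NWAT replicate 2 the median was 0.53 and 13 members were higher. The same library held red cell transcripts, with Hba-a1 at 83.6 CPM against 3.58 CPM in NWAT replicate 1 and Hbb-bs at 72.4 against 2.62, genes whose reads may be shared with their near-identical copies. Inflammatory cytokines and chemokines were higher for 8 of 24 and lower for 3, or 11 and 4 adjusted over the list alone. The median was 0.46 (camera adjusted p = 0.0327; adjusted p = 0.534 with an estimated correlation), with Cxcl10 (1.94 ± 0.33), Ptgs2 (0.95 ± 0.19) and Il6 (0.92 ± 0.18) higher and Cxcl12 (-0.59 ± 0.12) lower. Without single libraries, calls were lost for Cxcl10 (1.85 without SWAT replicate 2, 1.81 and 2.09 without EWAT replicates 1 and 2), Ptgs2 (1.0 and 0.90 without EWAT replicates 1 and 2, 0.88 without NWAT replicate 2), Il6 (0.73 without NWAT replicate 2) and Cxcl12 (-0.58 and -0.61 without NWAT replicates 1 and 2). That list's call was lost without SWAT replicate 1 (camera adjusted p = 0.0590), EWAT replicate 1 (0.174) or NWAT replicate 2 (0.222, median 0.26, 4 higher) and under fry (fry adjusted p = 0.153), within 0.00161 to 0.534 over 14 alternatives.

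Basement membrane genes were lower in NWAT for 12 of 19 and higher for 2, or 13 and 4 adjusted over the list alone. The median was -0.55 (camera adjusted p = 2.56e-04; adjusted p = 0.534 with an estimated correlation), with Col4a6 (-0.90 ± 0.10) and Col4a5 (-0.88 ± 0.10) lower and Nid1 (0.52 ± 0.11) and Agrn (0.41 ± 0.09) higher. Nid1 lost its call without NWAT replicate 1 (0.45), and Agrn without NWAT replicate 1 (0.44) or NWAT replicate 2 (0.38) and with the length trend removed (0.25). Fibrillar and interstitial matrix genes were lower for 12 of 29 and higher for 6, or 14 and 6 adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.0213; adjusted p = 0.483 with an estimated correlation), with Bgn (-1.11 ± 0.11) and Col1a1 (-0.81 ± 0.14; call lost on unfiltered log2 (FPKM + 1) values, -0.73) lower and Thbs1 (1.27 ± 0.13) and Col14a1 (1.02 ± 0.11) higher. Without NWAT replicate 2 that call was lost (camera adjusted p = 0.0959, within 0.00398 to 0.483), and without NWAT replicate 1 there were 7 lower. Col1a1 was lower still in EWAT, and Thbs1 was higher still there. By the median matrix member against its gene mean, NWAT (-0.11 and -0.18) lay between EWAT (-0.33 and -0.31) and SWAT (0.27 and 0.37). Complement genes were lower for 4 of 20 and higher for 2, over all genes and adjusted over the list alone. The median was -0.60 (camera adjusted p = 0.0213; adjusted p = 0.483 with an estimated correlation), with C7 (-2.04 ± 0.11) lower and Cd55 (0.96 ± 0.10) higher. The complement call was lost with a stricter filter (camera adjusted p = 0.160, within 0.00635 to 0.483), and its median was -0.36 without SWAT replicate 2 and -0.40 without NWAT replicate 2. Subcutaneous and limb-type patterning regulators were lower for 7 of 20 and higher for 3, or 9 and 3 adjusted over the list alone. The median was -0.55 (camera adjusted p = 0.0327; adjusted p = 0.534 with an estimated correlation), with Msx1 and Emx2 (-0.64 ± 0.15; call lost without NWAT replicate 2, -0.42, on log2 (FPKM + 0.1) values, -0.60, and on unfiltered log2 (FPKM + 1) values, -0.55) lower and En1 (1.17 ± 0.12) higher. That call was lost without SWAT replicate 1 (camera adjusted p = 0.0835), SWAT replicate 2 (0.0559) or EWAT replicate 1 (0.189) and with a stricter filter (0.638), within 0.0194 to 0.638, and without NWAT replicate 1 the median was -0.32 and 4 were lower.

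Markers of other cell types moved with NWAT as well. Mesothelial markers were higher for 9 of 13 members, or 10 with 1 lower adjusted over the list alone. The median was 1.71, or 1.29 at the bound (camera adjusted p = 5.69e-06; adjusted p = 0.483 with an estimated correlation), with Krt19 (2.07 ± 0.18), Rspo1 (0.90 ± 0.10) and Ezr (0.75 ± 0.09) as examples. Rspo1 and Ezr were higher still in EWAT. By the median mesothelial member against its gene mean, NWAT (0.39 and 0.22) lay below EWAT (0.40 and 0.52) and above SWAT (-0.69 and -0.61). Pericyte and smooth muscle markers were lower for 9 of 11 and higher for 1, over all genes and adjusted over the list alone. The median was -1.15 (camera adjusted p = 4.87e-04; adjusted p = 0.502 with an estimated correlation), with Myh11 (-2.85 ± 0.24) and Acta2 (-1.86 ± 0.43) lower and Myl9 (0.38 ± 0.10) higher. Acta2 lost its call without NWAT replicate 2 (-1.44) and on unfiltered log2 (FPKM + 1) values (-1.02). Myl9 lost its own without SWAT replicate 1 (0.38), SWAT replicate 2 (0.38), NWAT replicate 1 (0.27) or NWAT replicate 2 (0.48) and on the same FPKM values (0.43). Without SWAT replicate 2 the pericyte median was -0.72, and without NWAT replicate 2, 3 were lower. Macrophage and monocyte markers were lower for 3 of 16, and 5 adjusted over the list alone. The median was -0.77 (camera adjusted p = 4.87e-04; adjusted p = 0.534 with an estimated correlation), the 3 being Mrc1 (-1.46 ± 0.34), Csf1r (-1.17 ± 0.25) and Cd74 (-0.83 ± 0.17). All 3 lost their calls without NWAT replicate 2 (-1.21, -0.98 and -0.62). The macrophage call was lost with a stricter filter (camera adjusted p = 0.111, within 2.72e-08 to 0.534), and the median was -1.34 without NWAT replicate 1 and -0.38 without NWAT replicate 2. Endothelial markers were lower for 3 of 16 and higher for 2, or 7 and 3 adjusted over the list alone. The median was -0.62 (camera adjusted p = 0.0259; adjusted p = 0.534 with an estimated correlation), with Cdh5 (-0.61 ± 0.17), Vwf (-0.93 ± 0.26) and Egfl7 (-1.25 ± 0.38) lower and Prox1 (0.98 ± 0.21) and Tek (0.65 ± 0.11) higher. Cdh5 lost its call without any of the libraries but EWAT replicate 1 (-0.48 to -0.76), Egfl7 likewise (-0.94 to -1.65) and Vwf without SWAT replicate 2 (-0.81), EWAT replicate 2 (-0.78), NWAT replicate 1 (-1.06) or NWAT replicate 2 (-0.81), and DESeq2 called none of these 3. On unfiltered log2 (FPKM + 1) values these 3 genes also lost their calls (Cdh5 -0.29, Vwf -0.17 and Egfl7 -0.41), and limma-voom did not call Vwf or Egfl7. Prox1 lost its call without NWAT replicate 2 (0.91). That list's call was lost without SWAT replicate 1 (camera adjusted p = 0.0590) or NWAT replicate 1 (0.0618) and with a stricter filter (0.111), within 0.00832 to 0.534, and without EWAT replicate 1, 7 were lower. Oxidative phosphorylation genes had a median of -0.20 (camera adjusted p = 9.96e-04; adjusted p = 0.633 with an estimated correlation) with 0 of 28 members called by edgeR over all genes or adjusted over the list alone and 9 lower at an unadjusted p under 0.05. That list was not past the threshold without NWAT replicate 1 (camera adjusted p = 0.0644, median -0.12; within 6.11e-06 to 0.633), its median was -0.13 without EWAT replicate 2, and 13 members were lower without EWAT replicate 1. The fry test also called the visceral and coelomic list higher (fry adjusted p = 0.00700; camera adjusted p = 0.348) and the thermogenic list lower (0.0357; 0.281). It did not call the macrophage (fry adjusted p = 0.0922), endothelial (0.170) or oxidative phosphorylation list (0.260) in NWAT. By their median member, 10 of the 16 lists past the threshold had both NWAT libraries beyond the other 4. The exceptions were the mesothelial, macrophage, oxidative phosphorylation, fibrillar matrix, limb-type and inflammatory lists. All 16 were picked by a test on the same libraries. The limb-type medians of NWAT (-0.32 and -0.12) lay between those of EWAT (-0.69 and -0.81) and SWAT (1.15 and 0.84).

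**Figure D4:**
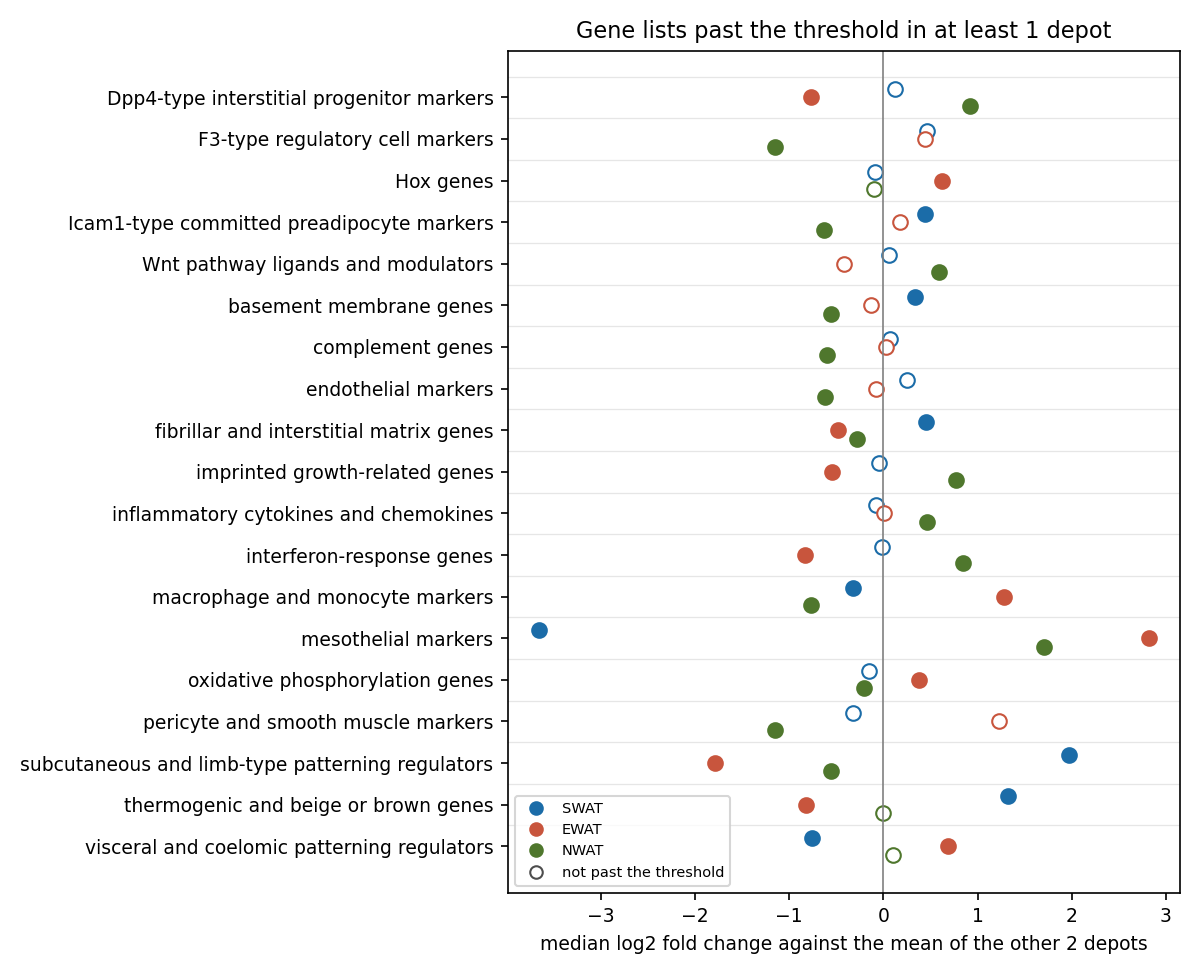
The median log2 fold change of each depot against the mean of the other 2 is plotted for the 19 gene lists past the camera threshold in at least 1 depot, with filled circles where the list was past it and open circles where it was not. Limb-type regulators have a median of 1.97 in SWAT and -1.79 in EWAT, and Dpp4-type markers one of 0.92 in NWAT and -0.76 in EWAT.

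Over all genes, edgeR called 2435 in NWAT against the mean of SWAT and EWAT, 1422 higher and 1013 lower, the lowest number of the 3 depots, and 773 were set apart from each other depot, 460 higher and 313 lower. These fell to 1251 and 445 without NWAT replicate 1 and to 1246 and 439 without NWAT replicate 2, and the genes set apart fell to 454 without SWAT replicate 2. On log2 (FPKM + 1) values, 66.5% of the calls in NWAT were higher, against 58.4% from the counts.

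Depots were also compared in pairs. SWAT against EWAT had the most calls, 5024 genes, 2472 higher and 2552 lower in SWAT. Under the same expression minimum, the 3 highest were Tbx15 (7.78 ± 0.22, edgeR adjusted p = 2.13e-09), Mmp3 (7.12 ± 0.28) and Itgb7, a leukocyte-type integrin gene (6.56 ± 0.32), and the 3 lowest were Wt1, Tcf21 and Hp (-8.33 ± 0.17, edgeR adjusted p = 4.65e-10). Between SWAT and NWAT, 2544 genes differed, 1238 higher and 1306 lower in SWAT, led by Wisp2 (4.88 ± 0.16, edgeR adjusted p = 1.57e-08), Abcc9 (4.85 ± 0.23) and Prg4 (4.03 ± 0.42), with Wt1, Tcf21 and Hp (-5.87 ± 0.16) lowest. Between EWAT and NWAT, 3726 genes differed, 1813 higher and 1913 lower in EWAT. Lrrn1 (5.63 ± 0.21, edgeR adjusted p = 8.85e-08), Myh11 (4.11 ± 0.24) and the angiotensinogen gene Agt (3.49 ± 0.13, with 361 CPM in EWAT and 32.2 in NWAT) were highest in EWAT, and Bmp3 (-5.06 ± 0.50), Akr1c18 (-4.85 ± 0.36) and Pcdh20 (-4.66 ± 0.17) lowest. The count for SWAT against EWAT fell to 3168 without SWAT replicate 1 and 3024 without SWAT replicate 2, below those of EWAT against NWAT in the same fits (3249 and 3242). That for SWAT against NWAT fell to 1559 and 1407 without the same libraries, 1552 without NWAT replicate 1 and 1473 without NWAT replicate 2. That for EWAT against NWAT fell to 2368 without EWAT replicate 2, 2086 without NWAT replicate 1 and 2225 without NWAT replicate 2. On log2 (FPKM + 1) values, 18.7% of the calls in SWAT against EWAT were higher, against 49.2% from the counts, with 18.7% against 48.7% for SWAT against NWAT and 58.9% against 48.7% for EWAT against NWAT.

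General markers of adipose progenitors were abundant in every library. Pdgfra, the receptor that marks adipose progenitors, stood at 1204 CPM ± 41.7 in SWAT, 1050 CPM ± 162 in EWAT and 1431 CPM ± 16.1 in NWAT (SD, n = 2), and Cd34 lay between 1267 and 1652 CPM. Thy1 was higher in SWAT (490 CPM, against 171 in EWAT and 274 in NWAT; 1.18 ± 0.09, edgeR adjusted p = 4.56e-06). Of 12 pan-progenitor markers, 4 were higher and 1 lower in SWAT, 3 higher and 6 lower in EWAT and 1 higher and 2 lower in NWAT, and the list was past the threshold in no depot (camera adjusted p = 0.513, 0.222 and 0.794), though fry called it lower in EWAT (fry adjusted p = 0.0370). Genes of mature adipocytes such as Adipoq stayed low, at 0.268, 0.430 and 0.867 CPM, and the 24 adipogenic regulators and adipocyte genes moved both ways (9 higher and 3 lower in SWAT, 7 and 8 in EWAT, 2 and 2 in NWAT; camera adjusted p = 0.890, 0.951 and 0.404). Endothelial Pecam1 stood at 5.69, 6.91 and 4.04 CPM in SWAT, EWAT and NWAT. Schwann and neural markers, 9 tested, were higher for 4 and lower for 2 in SWAT, with the myelin gene Mbp at 22.2 CPM in SWAT, 4.42 in EWAT and 15.8 in NWAT, and the list was past the threshold in no depot (camera adjusted p = 0.273, 0.158 and 0.860), though fry called it higher in SWAT (fry adjusted p = 0.0249) and lower in EWAT (0.0176). Fibroblastic reticular and lymph node stromal markers, 8 tested, were past it in none either (camera adjusted p = 0.935, 0.985 and 0.357). Proliferation genes, 26 tested, included 2 lower in SWAT, 1 higher and 1 lower in EWAT and 1 higher in NWAT (camera adjusted p = 0.426, 0.842 and 0.435), with Mki67 between 15.2 and 18.8 CPM. That list came past the threshold without EWAT replicate 1 in SWAT and EWAT, and without EWAT replicate 2 in EWAT and NWAT. Each of these fits leaves 1 library in EWAT. Their directions are not given here, so the calls cannot be read as agreeing.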

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

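The fits with the length or GC trend removed and the count of steady list members below were chosen only after the results were seen. Of the alternative values for the counts of genes and lists, 198 stayed within 1.5 times and 37 did not. Only totals were compared, so a changed split into higher and lower does not show in these numbers. With an absolute log2 fold change above 1, the counts were lower by construction: 2119 in the joint test, 1127 in SWAT, 1376 in EWAT, 685 in NWAT, 1618 for SWAT against EWAT, 918 for SWAT against NWAT, 1268 for EWAT against NWAT, and 585, 801 and 209 set apart in SWAT, EWAT and NWAT. With an estimated correlation, camera called 0, 0 and 0 lists in SWAT, EWAT and NWAT (5, 4 and 2 at an unadjusted p under 0.05, and 11, 15 and 15 called by fry). The Hox list in EWAT turned to the other direction under fry (fry adjusted p = 0.707), and the cause was not tested. Leaving out each library in turn gave 3994 to 6766 genes in the joint test, 2001 to 4683 in SWAT, 2994 to 5561 in EWAT, 1246 to 3579 in NWAT, 3024 to 5637 for SWAT against EWAT, 1407 to 3186 for SWAT against NWAT and 2086 to 4821 for EWAT against NWAT. Set apart were 918 to 1763 in SWAT, 1461 to 3384 in EWAT and 439 to 973 in NWAT, and past the threshold were 6 to 8, 10 to 14 and 13 to 17 lists. Such a fit has fewer samples, and the lone library is assumed to vary like the other depots. DESeq2 called 4834 genes in the joint test, limma-voom 5521, limma on log2 (FPKM + 1) values 6467 and the fit with the length trend removed 5772. The replicate block gave 5707 in the joint test, 3824 in SWAT, 4993 in EWAT, 2502 in NWAT, 5033, 2554 and 3779 for the pairs and 1611, 2469 and 811 set apart, and it changed no call of 93 list results and 217 named gene results. Samples share only a number, and replicate differences correlated by 0.000549 between SWAT and EWAT, 0.0375 between SWAT and NWAT and 0.110 between EWAT and NWAT. Over all alternatives, list results, called or not, stayed the same 1200 times. List calls were lost 80 times, gained 21 times and turned 1 time. Only 8, 11 and 16 of the 31 lists were called in SWAT, EWAT and NWAT, so many unchanged results had no call to lose. Calls of named genes stayed the same 3772 times and were lost 95 times, and not each of those losses is listed above. Oxidative phosphorylation genes came past the threshold in SWAT without EWAT replicate 1 (camera adjusted p = 0.00497), as did pericyte markers in EWAT without NWAT replicate 1 (0.0436). Among 401 called members of called lists, 262 kept their call without any 1 library and 242 under every alternative. For the 135 of them that the text names these numbers were 104 and 102, and for the 266 it does not name 158 and 140, so the named examples were steadier than their lists. Comparisons and settings that involve the mesenteric depot were not run. The simulation recovered 38 of 67 genes changed 1.5-fold and 51 of 67 changed 2-fold, so smaller changes were often missed there. It gave 182 calls for SWAT, against 3815 in the data, so its recovery need not hold for the data.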

Other observations

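All tests of explanations in this part were chosen only after the results were seen, while the gene lists were fixed before. Intervals in brackets after a share or a list median are 95% bootstrap intervals from 10000 draws over the list's members. These draws treat the members as independent, though members of a list moved together within a library. They also leave out the spread between libraries, so the intervals may be too narrow. Among retinoid genes, Cyp26b1, the enzyme that breaks down retinoic acid, stood at 152 CPM in SWAT, 2.24 in EWAT and 27.7 in NWAT (log2 fold change in SWAT 4.26 ± 0.15, edgeR adjusted p = 1.94e-08), and the alcohol dehydrogenase gene Adh7 at 25.0, 0.344 and 2.41 CPM (4.77 ± 0.15). Aldh1a1 was highest in EWAT (154 CPM, against 73.1 in SWAT and 73.6 in NWAT). Of 16 tested members, 6 were higher and 5 lower in SWAT, 6 and 4 in EWAT and 4 and 6 in NWAT (camera adjusted p = 0.817, 0.842 and 0.281), and fry called the list higher in SWAT (fry adjusted p = 0.0327). IGF, FGF and angiogenic factors, 27 tested, were higher for 10 and lower for 4 in SWAT, 6 and 11 in EWAT and 8 and 10 in NWAT (camera adjusted p = 0.176, 0.589 and 0.460), and fry called them higher in SWAT (fry adjusted p = 0.00880) and lower in NWAT (0.0108). Igfbp5, which binds insulin-like growth factors, stood at 5396 CPM in SWAT, 174 in EWAT and 2845 in NWAT, Igf1 at 423, 1029 and 371, Fgf1 at 4.21, 50.8 and 59.4 and Vegfa at 256, 85.9 and 167 CPM.

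BMP and TGF-beta genes, 30 tested, were higher for 10 and lower for 7 in SWAT, 10 and 9 in EWAT and 4 and 8 in NWAT (camera adjusted p = 0.273, 0.889 and 0.256). The inhibin subunit gene Inhbb stood at 3.45 CPM in SWAT, 61.6 in EWAT and 68.6 in NWAT, and the BMP antagonist gene Chrdl1 (154, 11 and 59.8 CPM) was highest in SWAT. Dissociation and heat-shock genes, 25 tested, moved both ways (9 higher and 6 lower in SWAT, 6 and 8 in EWAT, 5 and 4 in NWAT; camera adjusted p = 0.585, 0.842 and 0.858). Their levels were high, with Fosb at 9096, 4062 and 4673 CPM, Jun at 4844, 2852 and 2817 and Nr4a1 at 556, 1607 and 1520. Matrix proteases and inhibitors, 23 tested, were higher for 6 and lower for 6 in SWAT, 9 and 5 in EWAT and 3 and 5 in NWAT (camera adjusted p = 0.935, 0.842 and 0.319; higher in SWAT by fry, fry adjusted p = 0.0249), with Mmp2 at 3006, 1129 and 1378 CPM. Senescence-associated genes (14 tested; camera adjusted p = 0.371, 0.253 and 0.362) and hypoxia and glycolysis genes (21 tested; camera adjusted p = 0.303, 0.219 and 0.858) were past the camera threshold in no depot, and fry called the senescence list lower in EWAT (fry adjusted p = 0.0370). Markers of 8 further cell types, among them lymphocytes, epithelium and epididymis, had fewer than 5 tested members. The Y-linked gene Ddx3y stood at 98.5, 121 and 132 CPM, as the label male requires.

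Oxidative phosphorylation genes were higher in EWAT by a median log2 fold change of 0.37, in a depot whose fold changes fell with transcript length (Spearman -0.276) and whose replicate 2 differed most in this from its replicate 1 (-0.413, against 0.0688 in SWAT and -0.131 in NWAT). With the trend of each library on transcript length removed, the median was 0.23, 61% of its size (53 to 72.3). The list stayed past the threshold (camera adjusted p = 0.00129), with 9 members called in place of 18. The measured length trend thus did not account for the whole difference. Lengths were medians over annotated transcripts, so length bias that they miss stays open. Without EWAT replicate 2 the list's median was 0.16, 42.6% of that over all libraries (34.4 to 52.5). With 1 library left in EWAT, a trait of that library and a trait of the depot cannot be told apart. A biological difference between depots stays open as untested.

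Wt1 was high in EWAT and NWAT, and mesothelial cells in the sort could carry it. The summed CPM of the abundant mesothelial transcripts Msln, Upk3b, Krt8 and Krt18 was at most 3.63% of that of Wt1 in these libraries (range over the 4 libraries 2.01 to 3.63), which argues against such cells as its source. For trace transcripts of Msln, Upk3b, Upk1b, Gpm6a and Muc16, a test of whether their counts divide in 1 ratio between EWAT and NWAT (chi-square p = 0.00393) takes reads as independent and leaves out the spread between libraries, so it decides nothing. They rest on few counts, 56 and 32 for Msln and 25 and 40 for Muc16 in EWAT and NWAT, so a trace of mesothelial cells stays open for these 5 genes. Depot biology was not tested.

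Interferon-response genes were higher in NWAT by a median of 0.84. NWAT replicate 2 also held red cell transcripts such as Hba-a2 (50.3 CPM against 0.811 in replicate 1) and Alas2 (2.28 against 0.239). Without NWAT replicate 2 the median was 0.53, 63.6% of its size (56.7 to 77.8). Part of this remainder reflects low levels in EWAT. Against the mean of all libraries, the interferon median was 0.30 in NWAT replicate 1, -0.04 and 0.05 in SWAT and -0.56 and -0.51 in EWAT. NWAT replicate 1 thus lay above every SWAT and EWAT library, so this order did not rest on replicate 2 alone. With 1 library left in NWAT, a trait of that library and a trait of the depot cannot be told apart. Macrophage and monocyte markers had a median of -0.766 (-0.873 to -0.359) in NWAT. Against the mean of all libraries they were lowest in NWAT replicate 2 (-0.93) and highest in EWAT (0.80 in both), where interferon genes were lowest (-0.56 and -0.51). That argues against macrophages and monocytes in the sort as the source of the higher interferon levels in NWAT than in EWAT. For NWAT against SWAT these cells stay open, because the macrophage median of NWAT replicate 1 (-0.13) lay above those of SWAT (-0.43 and -0.14). Other leukocytes were not tested. The rule for this test was rewritten after its value was seen, and a version that asked both NWAT libraries to lie beyond the other 4 left these cells open. A difference between depots stays open as untested.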
